A study of Mus musculus with 12 samples.

How the data were processed

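Gene expression was measured in mouse D3 embryonic stem cells on 12 Affymetrix mouse arrays, 3 for each of 4 culture conditions. Per the labels' protocols, cells were grown for 7 days in serum-containing medium with or without LIF at 1000 units per ml and with or without lithium, whose concentration the labels give as 50 nM. The labels number the arrays of each condition as biological replicates 1 to 3 and do not say whether a number marks a shared day or culture. The deposited values are MAS5 signal intensities per probe set on a linear scale, made by the authors with Affymetrix MAS5 per the submitters' processing notes, which state no version and no settings. The mean of each array without its lowest and highest 2% of values was 100 (99.96 to 99.966), so each array had been scaled to one target.

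The table holds 45101 probe sets, of which 64 Affymetrix controls were left out. Values under 1 were set to 1 (0.146% of the values tested) and log2 was taken. A probe set was tested where its mean log2 value over all 12 arrays was above the 40th percentile (a signal of 7.52), which kept 27022. The size of a log2 change from a mean under that signal rests on values near background. Gene symbols came from the platform annotation table, in which 34945 probe sets have 1 symbol, 932 several and 9160 none, the last unnamed here. A reference table of mouse gene names was used to update symbols by gene ID: 34741 matched and 0 changed. No probe set with several symbols was named. A gene was represented by its brightest kept probe set, with cross-hybridising _x_at sets used only where a gene had no other. Of 6042 genes with at least 2 kept probe sets, 2, 5 and 1 had sets called in opposite directions in withdrawal without lithium, withdrawal with lithium, and lithium without LIF against LIF alone.

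One linear model with a mean per condition was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend, 8 residual degrees of freedom). All tests were two-sided, and p values were adjusted by Benjamini-Hochberg over the 27022 probe sets of a comparison, with a threshold of 0.05. The 7 comparisons were LIF withdrawal without and with lithium, lithium with and without LIF, the interaction, the average lithium effect, and lithium without LIF against LIF alone. With 3 arrays against 3 a permutation of labels cannot give a two-sided p under 0.1, so the model's pooled spread carries every call. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.

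A set of 22 gene lists was written before the data were examined: pluripotency network, LIF-STAT3 targets, Wnt-beta-catenin targets, Wnt ligands and receptors, primitive streak, cardiac and lateral mesoderm, endoderm, neural, primed epiblast, trophoblast, fibroblasts and feeder cells, endothelium and blood, germ cells and 2-cell-like cells, epithelial-mesenchymal, Hox, cell cycle, p53 targets, stress, glycolysis and hypoxia, cholesterol biosynthesis, imprinted genes, and lithium-sensitive enzymes. Each was tested by camera with a preset correlation of 0.01 and with an estimated one, and by fry. Lists of interferon-stimulated and class I antigen presentation genes were written after the data were seen.

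Named genes followed a rule set beforehand. Among called genes whose values did not overlap between conditions, the 10 largest rises and 10 largest falls were named, passing over symbols ending in Rik or starting with LOC or with Gm and a digit (30, 42 and 29 passed over in the comparisons with calls). Where none passed, the 3 with the smallest p were named. Up to 4 members per list were those past the threshold with the smallest p, and for withdrawal with lithium and the last comparison only part of the lists and members is printed. Pou5f1, Nanog, Sox2, Zfp42, Klf4, Esrrb, Socs3, Axin2, T, Gata6 and Fgf5 were named whatever their values. Lin28a, Tcl1b3 and the members of the later lists were chosen after their values were seen.

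Whether equal replicate numbers pair the arrays was checked, before any blocked fit was read, by correlating array residuals from their condition means across probe sets for each of 6 pairs of conditions. The numbers come from the labels, and a pair was accepted where all 3 correlations passed 0.1. For replicates 1, 2 and 3 the correlations were 0.438, 0.137 and 0.339 between LIF and LIF-free, 0.499, 0.139 and 0.321 between LIF and LIF plus lithium, and 0.462, 0.111 and 0.3 between LIF-free and LIF-free plus lithium. These comparisons count as paired, and the blocked value stands beside a call it changed and beside a count of called probe sets or list members it moved over 1.5 times.

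Alternatives were quantile normalisation, centring each array on its median, a pseudocount of 16, no filter, a filter at the 60th percentile, the replicate number as a block, no intensity trend, array weights, only the arrays of the compared conditions, the mean over a gene's probe sets for lists, an estimated correlation, and leaving out each array. A gene or list counted as reversed only where a called value had the opposite sign. Similarity of comparisons that share a condition was set beside 20 simulations of unchanged groups, drawn without the pairing of replicate numbers. Conditions of 3 arrays cannot be divided into parts of at least 2, so part of any excess can come from shared arrays.

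The model was run on simulated data with the measured spread and 200 of 27022 probe sets changed. At 2-fold it recovered 21% and 16% in withdrawal without and with lithium, and 21.5% and 26.5% for lithium with and without LIF. Recovery was 2% for the interaction, 28.5% for the last comparison and 40% for the average effect. In that order it was 67.5%, 66.5%, 70.5%, 69%, 52%, 71% and 85% at 4-fold and 0%, 0%, 0%, 1.5%, 0%, 0% and 8% at 1.5-fold. With pairing or far more calls, recovery is unknown. Probe-level array files, detection calls and probe sets without a symbol were not used here beyond the counts of calls.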

Results

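Mouse D3 embryonic stem cells were profiled on 12 expression arrays after 7 days of culture. There were 3 arrays for each of 4 conditions: LIF at 1000 units per ml, LIF plus lithium, no LIF (LIF-free), and no LIF but lithium (LIF-free plus lithium). LIF holds mouse embryonic stem cells in self-renewal through its receptor and the transcription factor STAT3. Lithium inhibits the kinase GSK3, which marks beta-catenin for breakdown, and is used to mimic a Wnt signal. The labels give its concentration as 50 nM, while millimolar levels are usual, so whether GSK3 was inhibited in these cultures is not known. The design asks what LIF withdrawal changes, what lithium changes, and whether each alters the effect of the other. Every array was deposited as MAS5 signal per probe set, and 27022 of 45037 probe sets, standing for 12737 named genes, were bright enough to be tested. Median signal per array ran from 10.5 to 19.3, and the log2 signals of any pair of arrays correlated across probe sets with r from 0.875 to 0.953. Without the block, the median half-width of a 95% interval of a log2 change was 0.63 over all tested probe sets and 0.48 over the 18015 brighter. The comparisons, gene lists, threshold and naming rule were set before the data were examined. Brachyury (T) has no probe set of that name here.

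Withdrawal of LIF takes away the signal that keeps serum-grown embryonic stem cells undifferentiated. The first comparison asked which transcripts of the pluripotent state were lost, and which of the epiblast and early lineages were gained, in LIF-free against LIF cultures without lithium. Transcripts of the naive pluripotency network, of the activin subunit Inhbb and of some germ cell genes fell. A primed-epiblast growth factor, simple-epithelium keratins and several imprinted and Wnt target genes rose. limma called 2515 probe sets at an adjusted p under 0.05, 1458 higher and 1057 lower without LIF, and 1414 of them changed at least 2-fold. By gene, 921 were higher and 659 lower. All 3 values of one condition lay above all 3 of the other in 4080 genes (32.0%), where chance gives 10%. With the replicate number as a block, 5260 probe sets were called. The count was 3950 without LIF replicate 1, 1075 without LIF replicate 2 and 1506 without LIF replicate 3. It was 1324 without LIF-free replicate 1, 1039 without LIF-free replicate 2 and 1569 without LIF-free replicate 3. The split depended on the scaling between arrays: 58.0% of calls were higher as deposited, and 83.1% of 1560 calls after centring each array on its median. Centring moved the median log2 change of all tested probe sets from -0.07 to 0.13. No probe set called as deposited changed sign under either alternative scaling. Array quality measures moved with LIF too: the Gapdh 3 prime to 5 prime ratio was 0.816 with LIF and 0.764 in LIF-free arrays (values not overlapping), that of actin 1.77 and 1.55, and the 18S signal 659 ± 649 and 1182 ± 244. Their part in the calls was not tested.

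Among called genes without overlapping values, Fgf5, a growth factor of the primed epiblast, had the largest log2 rise, from low LIF signals (signal 12.7 ± 17.2 to 122 ± 18.9, mean ± SD, n = 3 arrays per condition, log2 change 4.38 ± 1.13, adjusted p = 0.0291). Aplnr, the apelin receptor of early mesoderm, rose from 29.2 ± 36.3 to 297 ± 131 (log2 change 4.27, adjusted p = 0.0402). Cyp26a1, which breaks down retinoic acid, rose from 18.7 ± 15.9 to 202 ± 73.3 (log2 change 3.68, adjusted p = 0.00252). Rises were also large in Foxa1, a forkhead factor of endoderm (log2 change 3.54, adjusted p = 0.0266) and Lhx1, a homeobox factor of the node (log2 change 3.46, adjusted p = 0.0267). The interferon-induced genes Rtp4, a receptor chaperone (log2 change 3.55, adjusted p = 0.0273) and Usp18, which strips ISG15 from proteins (log2 change 3.47, adjusted p = 0.0153) rose. The 10 were completed by Vdr, the vitamin D receptor (log2 change 3.45, adjusted p = 0.00239), Rspo3, an amplifier of Wnt signals (log2 change 3.40, adjusted p = 0.0423) and Tnni2, a fast-muscle troponin (log2 change 3.38, adjusted p = 0.0277). The largest log2 falls were in Myo1f, an unconventional myosin (signal 61.9 ± 19.1 to 1.01 ± 0.258, close to the floor of 1 that the fold rests on, log2 change -5.77 ± 0.57, adjusted p = 0.000776), and Inhbb, a subunit of activin B (signal 155 ± 73.6 to 3.02 ± 1.42, log2 change -5.66 ± 0.57, adjusted p = 0.000776). Etv4, an ETS factor induced by FGF, fell from 117 ± 38.6 to 9.21 ± 6.22 (log2 change -4.02, adjusted p = 0.00421). The protease inhibitor A2m fell from 142 ± 43.8 to 14 ± 8.46 (log2 change -3.47, adjusted p = 0.00101). Falls were also large in Ttc29, a sperm flagellum protein (log2 change -5.19, adjusted p = 0.00203), Ucp1, the uncoupling protein of brown fat (log2 change -4.60, adjusted p = 0.00187) and Arc, a synaptic immediate early protein (log2 change -4.32, adjusted p = 0.00995). Vax2os, a transcript opposite Vax2 (log2 change -3.77, adjusted p = 0.00493), Ampd3, an AMP deaminase (log2 change -3.48, adjusted p = 0.018) and Slc47a1, an exporter of organic cations (log2 change -3.28, adjusted p = 0.000776) completed the falls. Their log2 changes shrank, with 16 signal units added before the log, to between 1.12 and 3.0 for the rises and -3.08 and -1.31 for the falls. The order changed: Fgf5 (2.41) came behind Aplnr, Cyp26a1 (2.68) and Usp18 (2.48), and Myo1f (-2.16) behind Inhbb, A2m (-2.40) and Etv4 (-2.39). Calls that single arrays ended (their number, highest adjusted p) were Fgf5 (5, 0.113), the highest p without LIF replicate 3. For Aplnr (8, 0.161), Foxa1 (5, 0.0976), Usp18 (3, 0.0672), Rspo3 (9, 0.162), Tnni2 (4, 0.102), Arc (1, 0.0532) and Ampd3 (2, 0.0749) it was reached without LIF replicate 2. For Lhx1 (4, 0.115) and Rtp4 (5, 0.0886) it was reached without LIF-free replicate 2.

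Among pluripotency genes, 30 were measured, of which 0 rose, 22 fell and 8 did not pass, or 1 and 25 adjusted over the list alone. Log2 changes of pluripotency genes had a median of -1.13 (camera adjusted p = 7.2e-15, 0.209 with an estimated correlation). Klf4, a naive-state factor driven by STAT3, fell from 1531 ± 395 to 321 ± 68.3 (log2 change -2.24 ± 0.23, adjusted p = 0.000776). Falls were called for Tfcp2l1, which relays LIF to the naive network (log2 change -1.58, adjusted p = 0.000776), Tet2, which oxidises methylated cytosine (log2 change -2.05, adjusted p = 0.000776) and Tdgf1, the Nodal co-receptor Cripto (log2 change -1.85, adjusted p = 0.00101). Pou5f1, the Oct4 gene, fell from 2281 ± 989 to 795 ± 129 (log2 change -1.44 ± 0.29, adjusted p = 0.0101). Sox2, its partner on DNA, fell from 2767 ± 573 to 1339 ± 295 (log2 change -1.05, adjusted p = 0.0266). Pou5f1 (adjusted p = 0.0792), Sox2 (adjusted p = 0.236) and Zfp42 (adjusted p = 0.0929) missed the threshold after median centring. Lower, too, were Zfp42, the stem cell marker Rex1 (log2 change -1.11, adjusted p = 0.0023) and Esrrb, an orphan nuclear receptor (log2 change -1.91, adjusted p = 0.00467). Nanog, a homeobox factor of the naive state, did not pass (log2 change -0.83 ± 0.30, adjusted p = 0.105), although it did with the replicate number as a block (adjusted p = 0.00302). Of LIF-STAT3 targets, 0 of 21 measured members rose, 8 fell and 13 did not pass. LIF-STAT3 members that rose and fell adjusted over the list alone numbered 0 and 10 (median log2 change -0.54, camera adjusted p = 3.91e-07, 0.209 with an estimated correlation). Socs3, the feedback inhibitor of LIF signalling, fell from 349.7 ± 196 to 72.6 ± 8.36 (log2 change -2.13, adjusted p = 0.00158). Gbx2, a homeobox target of STAT3 (log2 change -2.67, adjusted p = 0.00158) fell as well. Not kept with 1 array left out (number of such arrays, highest adjusted p) were Sox2 (4, 0.1), the highest p without LIF-free replicate 1.

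**Figure D1:**
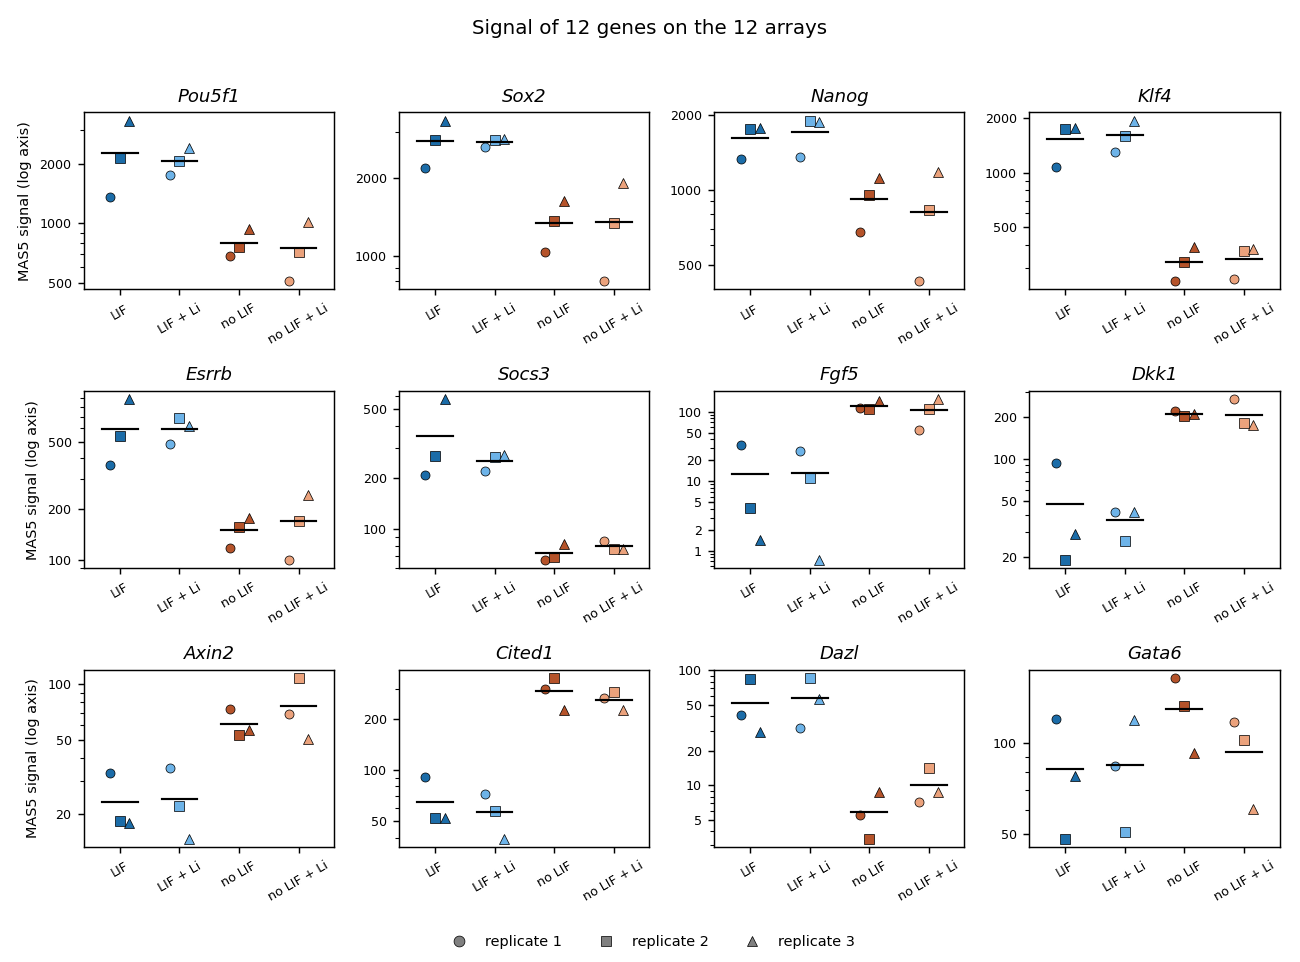
MAS5 signal (arbitrary units, log axis) of 12 genes in the 4 culture conditions. Each symbol is 1 array (circle, square and triangle for replicates 1, 2 and 3) and each bar is the mean of 3 arrays, and Pou5f1 runs from a mean of 2281 with LIF to 795 without it.

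Wnt signalling acts through beta-catenin on target genes that include its own inhibitors. Of those targets, 5 members rose, 0 fell (10 and 0 with the block) and 14 did not pass among 19 measured, or 11 and 0 adjusted over the list alone. The Wnt target median log2 change was 1.12 (camera adjusted p = 3.84e-05, 0.286 with an estimated correlation). Dkk1, a secreted Wnt antagonist, rose from 47.3 ± 40.6 to 209.7 ± 8.07 (log2 change 2.49, adjusted p = 0.00482). Axin2, a scaffold of the beta-catenin destruction complex, rose from 23.1 ± 8.76 to 61.1 ± 10.5 (log2 change 1.45, adjusted p = 0.03). Rises were called as well for Tnfrsf19, a TNF receptor family member (log2 change 2.56, adjusted p = 0.00991) and Evx1, a homeobox factor of the late streak (log2 change 3.36, adjusted p = 0.0394). Of Wnt ligands and receptors, 6 of 25 measured members rose, 1 fell (10 and 2 with the block) and 18 did not pass. Wnt ligand members that rose and fell adjusted over the list alone numbered 11 and 2 (median log2 change 0.29, camera adjusted p = 0.0056, 0.345 with an estimated correlation). Higher members were Wnt9a, a ligand (log2 change 1.40, adjusted p = 0.00349), Dact1, a Dishevelled antagonist (log2 change 1.53, adjusted p = 0.00561), Fzd2, a Frizzled receptor (log2 change 1.51, adjusted p = 0.0088) and Ror1, a Wnt5a receptor (log2 change 1.91, adjusted p = 0.0169). With 1 array left out, calls ended (number of such arrays, highest adjusted p) for Axin2 (5, 0.11), Evx1 (7, 0.148) and Ror1 (4, 0.0745), the highest p without LIF replicate 2.

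Cells leaving pluripotency pass through a primed epiblast before they form the germ layers. Among primed-epiblast genes, 17 were measured, of which 4 rose, 1 fell (7 and 2 with the block) and 12 did not pass, or 8 and 2 adjusted over the list alone. Log2 changes of primed-epiblast genes had a median of 0.83 (camera adjusted p = 0.0207, 0.345 with an estimated correlation). Besides Fgf5, Sox4, an HMG-box factor (log2 change 1.70, adjusted p = 0.00819) and Cldn6, a claudin of embryonic epithelia (log2 change 0.99, adjusted p = 0.0123) rose. In the primitive streak list, 4 members rose, 1 fell (7 and 1 with the block) and 9 did not pass among 14 measured, or 7 and 1 adjusted over the list alone. The streak median log2 change was 1.2 (camera adjusted p = 0.0232, 0.274 with an estimated correlation). Foxa2, a forkhead factor of node and endoderm (log2 change 1.27, adjusted p = 0.0191) rose, and Lefty2, a Nodal antagonist held in both lists (log2 change -1.0, adjusted p = 0.016) fell. For cardiac and lateral mesoderm, 1 of 18 measured members rose, 0 fell (5 and 0 with the block) and 17 did not pass. Cardiac members that rose and fell adjusted over the list alone numbered 4 and 0 (median log2 change 0.57, camera adjusted p = 0.0248, 0.345 with an estimated correlation). The riser was Tbx20, a T-box factor of the heart (log2 change 1.25, adjusted p = 0.00874). The primed-epiblast call ended without LIF replicate 3 (adjusted p = 0.0622). The cardiac call ended without LIF replicate 2 (adjusted p = 0.0763), LIF replicate 3 (adjusted p = 0.0534) or LIF-free replicate 1 (adjusted p = 0.125). In the Hox list, 13 were measured, of which 2 rose, 0 fell and 11 did not pass, or 2 and 0 adjusted over the list alone. Log2 changes of Hox genes had a median of 0.98 (camera adjusted p = 0.0207, 0.345 with an estimated correlation). The risers were the Hox cofactors Meis2 (log2 change 2.15, adjusted p = 0.0303) and Meis1 (log2 change 1.45, adjusted p = 0.034). The Hox call ended without LIF replicate 2 (adjusted p = 0.119) or LIF-free replicate 1 (adjusted p = 0.0731). Calls that single arrays ended (their number, highest adjusted p) were Cldn6 (1, 0.0586), Foxa2 (4, 0.0859) and Lefty2 (4, 0.0643), the highest p without LIF-free replicate 2. For Meis2 (5, 0.128) and Meis1 (5, 0.132) it was reached without LIF replicate 2.

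In the trophoblast list, 7 members rose, 0 fell (12 and 0 with the block) and 8 did not pass among 15 measured, or 13 and 0 adjusted over the list alone. The trophoblast median log2 change was 1.18 (camera adjusted p = 1.01e-08, 0.209 with an estimated correlation). Krt18, a keratin of simple epithelia, rose from 2209 ± 477 to 5990 ± 692 (log2 change 1.46, adjusted p = 0.00158). Its partner Krt8 (log2 change 1.60, adjusted p = 0.00203) rose, as did Krt7, another simple keratin (log2 change 1.33, adjusted p = 0.00201) and Gata3, a trophoblast factor (log2 change 2.09, adjusted p = 0.00465). For primitive and visceral endoderm, 3 of 25 measured members rose, 1 fell (5 and 3 with the block) and 21 did not pass. Endoderm members that rose and fell adjusted over the list alone numbered 5 and 4 (median log2 change 0.26, camera adjusted p = 0.383). Cited1, a coactivator of visceral endoderm, rose from 65.1 ± 22.2 to 291 ± 61.3 (log2 change 2.19, adjusted p = 0.00122), with Sparc, a matrix protein (log2 change 0.90, adjusted p = 0.00679). Amn, an endocytic receptor (log2 change -1.37, adjusted p = 0.0399) fell, and the endoderm factor Gata6 did not pass (log2 change 0.72, adjusted p = 0.275). In the neural list, 15 were measured, of which 2 rose, 2 fell and 11 did not pass, or 2 and 2 adjusted over the list alone. Log2 changes of neural genes had a median of 0.32 (camera adjusted p = 0.82). Gap43, a growth-cone protein (log2 change 2.01, adjusted p = 0.0131) and Sox11, a factor of immature neurons (log2 change 1.60, adjusted p = 0.0137) rose, whereas Neurod1, a proneural factor (log2 change -2.51, adjusted p = 0.00638) and Stmn2, a neuronal tubulin binder (log2 change -0.83, adjusted p = 0.0101) fell. Of fibroblast and feeder cell markers, 2 members rose, 0 fell (6 and 1 with the block) and 11 did not pass among 13 measured, or 3 and 1 adjusted over the list alone. The fibroblast median log2 change was 1.13 (camera adjusted p = 0.00767, 0.345 with an estimated correlation). The risers were Col5a1, a collagen (log2 change 1.62, adjusted p = 0.0119) and Cxcl12, a chemokine (log2 change 2.61, adjusted p = 0.0206). Among endothelial and blood genes, 0 of 9 measured members rose, 0 fell and 9 did not pass. Blood members that rose and fell adjusted over the list alone numbered 0 and 0 (median log2 change 0.45, camera adjusted p = 0.857). Smallest in p were Hbb-bh1 (log2 change 1.76, adjusted p = 0.184) and Runx1 (log2 change -0.97, adjusted p = 0.192). Not kept with 1 array left out (number of such arrays, highest adjusted p) were Amn (5, 0.15) and Stmn2 (1, 0.0551), the highest p without LIF-free replicate 2. For Gap43 (3, 0.0594), Sox11 (3, 0.0671), Col5a1 (2, 0.0605) and Cxcl12 (4, 0.074) it was reached without LIF replicate 2.

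In the germ cell list, 0 members rose, 4 fell and 6 did not pass among 10 measured, or 0 and 6 adjusted over the list alone. The germ cell median log2 change was -1.18 (camera adjusted p = 0.00175, 0.345 with an estimated correlation). Dazl, an RNA-binding protein of germ cells, fell from 51.8 ± 29 to 5.89 ± 2.66 (log2 change -3.09, adjusted p = 0.00339). Mael, a transposon-silencing protein (log2 change -2.36, adjusted p = 0.00703), Stra8, a meiosis factor (log2 change -2.15, adjusted p = 0.00988) and Ddx4, the Vasa helicase (log2 change -1.2, adjusted p = 0.0319) also fell. In the epithelial-mesenchymal list, 8 of 21 measured members rose, 0 fell (13 and 0 with the block) and 13 did not pass. Epithelial-mesenchymal members that rose and fell adjusted over the list alone numbered 12 and 0 (median log2 change 0.82, camera adjusted p = 1.29e-05, 0.271 with an estimated correlation). The tight-junction genes Cldn7 (log2 change 1.04, adjusted p = 0.00583), Cldn3 (log2 change 1.35, adjusted p = 0.00609) and Ocln (log2 change 1.23, adjusted p = 0.0068) rose together with the mesenchymal filament Vim (log2 change 1.5, adjusted p = 0.0146). Among imprinted genes, 19 were measured, of which 9 rose, 0 fell and 10 did not pass, or 14 and 0 adjusted over the list alone. Log2 changes of imprinted genes had a median of 1.03 (camera adjusted p = 9.01e-07, 0.28 with an estimated correlation). Cdkn1c, a maternally expressed cell cycle inhibitor (log2 change 2.15, adjusted p = 0.00244) rose, and so did the paternally expressed Sgce (log2 change 1.37, adjusted p = 0.00399), Peg10 (log2 change 2.05, adjusted p = 0.0068) and Ndn (log2 change 1.42, adjusted p = 0.00896). In the cell cycle list, 1 member rose, 3 fell (1 and 6 with the block) and 22 did not pass among 26 measured, or 1 and 3 adjusted over the list alone. The cell cycle median log2 change was -0.16 (camera adjusted p = 0.0401, 0.32 with an estimated correlation). Median centring turned this median to 0.03 (adjusted p = 0.296). Ccne1, cyclin E1 (log2 change -0.97, adjusted p = 0.00203), Bub1b, a spindle checkpoint kinase (log2 change -0.78, adjusted p = 0.00649) and Mcm3, a helicase subunit (log2 change -0.60, adjusted p = 0.0373) fell, and Ccne2, cyclin E2 (log2 change 1.03, adjusted p = 0.0464) rose. The cell cycle call ended without LIF replicate 2 (adjusted p = 0.116), LIF-free replicate 1 (adjusted p = 0.0696) or LIF-free replicate 2 (adjusted p = 0.077). With 1 array left out, calls ended (number of such arrays, highest adjusted p) for Ddx4 (5, 0.133), Vim (3, 0.0606) and Mcm3 (7, 0.128), the highest p without LIF replicate 2. For Ccne2 (10, 0.142) it was reached without LIF replicate 3.

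For glycolysis and hypoxia, 0 of 24 measured members rose, 3 fell (1 and 11 with the block) and 21 did not pass. Glycolysis members that rose and fell adjusted over the list alone numbered 1 and 7 (median log2 change -0.35, camera adjusted p = 0.00105, 0.345 with an estimated correlation). Pfkp, the platelet phosphofructokinase, fell from 1032 ± 165 to 235 ± 57.6 (log2 change -2.15, adjusted p = 0.000776), as did Hk2, hexokinase 2 (log2 change -0.85, adjusted p = 0.00346) and Ak4, an adenylate kinase (log2 change -0.75, adjusted p = 0.0328). In the stress list, 25 were measured, of which 2 rose, 5 fell (4 and 7 with the block) and 18 did not pass, or 3 and 6 adjusted over the list alone. Log2 changes of stress genes had a median of -0.20 (camera adjusted p = 0.383). Atf3, a stress-induced factor (log2 change 1.44, adjusted p = 0.00203) and Dnajb1, a heat-shock co-chaperone (log2 change 0.76, adjusted p = 0.0149) rose, while the ATF4 targets Trib3 (log2 change -1.33, adjusted p = 0.00737) and Chac1 (log2 change -1.10, adjusted p = 0.0198) fell. Among p53 targets, 1 member rose, 0 fell (2 and 1 with the block) and 13 did not pass among 14 measured, or 1 and 0 adjusted over the list alone. The p53 median log2 change was 0.06 (camera adjusted p = 0.457). The riser was Perp, a desmosome protein (log2 change 1.01, adjusted p = 0.0169). For cholesterol biosynthesis, 0 of 16 measured members rose, 0 fell (2 and 0 with the block) and 16 did not pass. Cholesterol members that rose and fell adjusted over the list alone numbered 0 and 0 (median log2 change 0.11, camera adjusted p = 0.337). Its members Sc5d (adjusted p = 0.0973) and Hsd17b7 (adjusted p = 0.104) passed with the replicate number as a block (adjusted p = 0.0129 and 0.031). Of lithium-sensitive enzymes and inositol metabolism, 16 were measured, of which 1 rose, 0 fell (3 and 2 with the block) and 15 did not pass, or 1 and 0 adjusted over the list alone. Log2 changes of lithium enzyme genes had a median of 0.19 (camera adjusted p = 0.262). The riser was Marcks, a kinase C substrate (log2 change 1.18, adjusted p = 0.0127). Calls that single arrays ended (their number, highest adjusted p) were Ak4 (4, 0.134) and Perp (3, 0.0645), the highest p without LIF-free replicate 2. For Dnajb1 (1, 0.0502) it was reached without LIF-free replicate 1. For Chac1 (2, 0.0816) and Marcks (2, 0.0641) it was reached without LIF replicate 2.

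Of the 22 lists, camera called 15 in this comparison, 10 up and 5 down, and with an estimated correlation between genes it called 0. The rotation test fry, which asks whether a list's genes moved one way on balance, called 12. Of 83 named genes that passed, 49 passed whichever single array was left out, 50 under all other alternatives and 43 throughout. Median centring ended 15 of these calls. Leaving out LIF replicates 1, 2 and 3 ended 1, 30 and 27 of these calls, and leaving out LIF-free replicates 1, 2 and 3 ended 24, 27 and 14. The lithium arrays, which add only to the estimate of spread, ended 0, 3 and 1 (LIF plus lithium) and 4, 6 and 3 (LIF-free plus lithium). With 16 signal units added before the log, other changes that moved over 1.5-fold were -2.04 for Gbx2, 1.27 for Evx1, 1.25 for Ror1, 0.82 for Meis1, 1.26 for Gata3, -1.07 for Neurod1, 1.61 for Cxcl12, -1.55 for Dazl and -1.48 for Stra8 (log2 change).

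**Figure D2:**
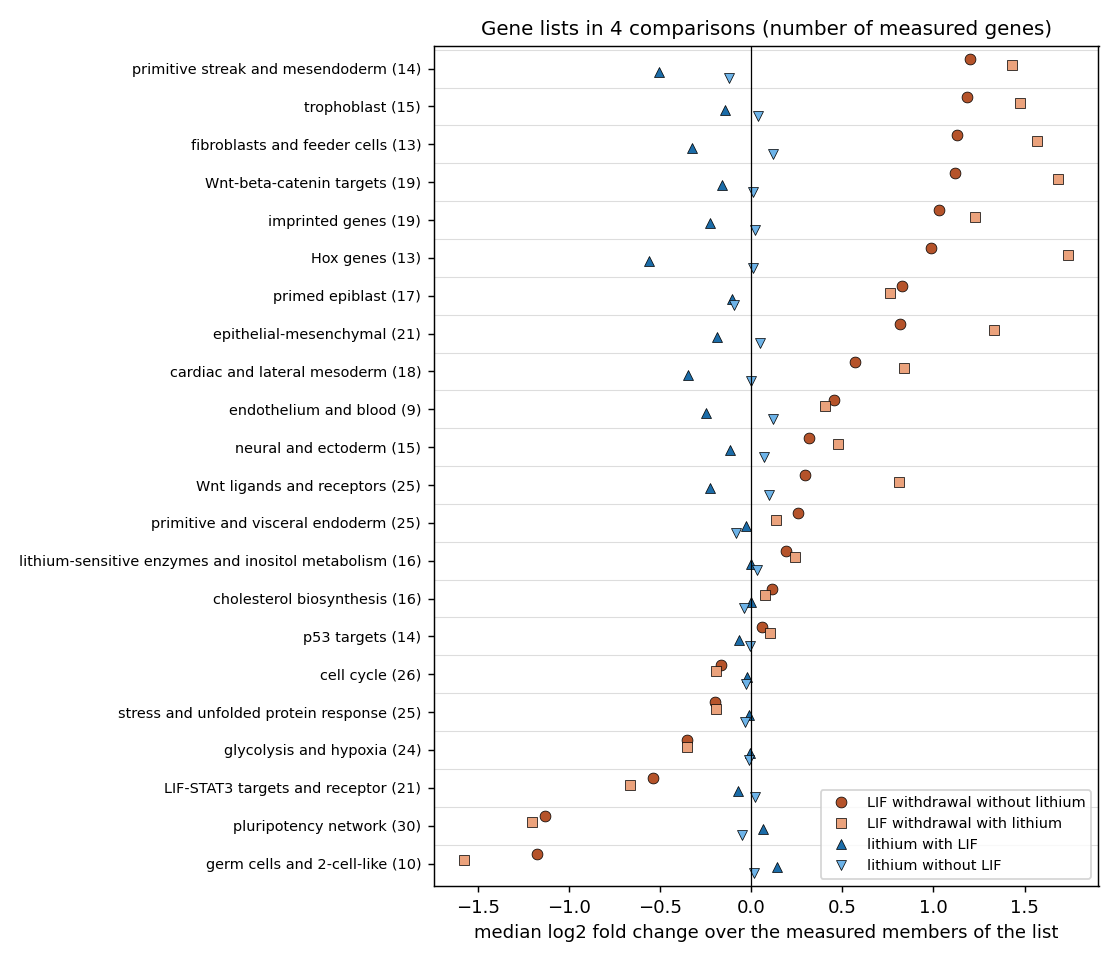
Median log2 change of the measured members of 22 gene lists (one line per list) in the comparisons of LIF withdrawal without and with lithium and of lithium with and without LIF. The pluripotency list lies at -1.13 for withdrawal without lithium and at -1.2 for withdrawal with lithium.

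Lithium was present on both sides of the second comparison, which asked what LIF withdrawal changed in cells exposed to it. Transcripts of the naive network fell here as well, Nanog included. The largest log2 rises included Aplnr, Cdh11 and Nrp1, and simple keratins and several Wnt target and imprinted genes were higher without LIF. limma called 3368 probe sets, 2035 higher and 1333 lower without LIF, and 1926 of them changed at least 2-fold. By gene, 1205 were higher and 833 lower. In 5084 genes (39.9%) the 3 values of one condition all lay above the 3 of the other, where chance gives 10%. The count was 1806 without LIF plus lithium replicate 2 and 1360 without LIF plus lithium replicate 3. It was 1499 without LIF-free plus lithium replicate 1 and 1522 without LIF-free plus lithium replicate 2. Median centring turned the split over, from 60.4% of calls higher to 34.8% of 1490 calls. It moved the median log2 change of all tested probe sets from 0.11 to -0.23, so that small rises of lists are relative to the deposited scaling. The Gapdh ratio was 0.832 with LIF and 0.783 without, and the 18S signal 309 ± 350 and 1077 ± 642, with overlap.

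Aplnr rose most (signal 9.31 ± 15.6 to 228 ± 63, mean ± SD, n = 3, log2 change 6.20 ± 1.19, adjusted p = 0.00572). Lhx1 rose from 0.778 ± 0.358 to 49.1 ± 25.2, from under the floor of 1 that the fold rests on (log2 change 5.47, adjusted p = 0.00236). Nrp1, a co-receptor for VEGF and semaphorins, rose from 10.9 ± 10.2 to 211 ± 136 (log2 change 4.57, adjusted p = 0.00493). Rises of mesenchymal genes included Cdh11, a cadherin (log2 change 5.44, adjusted p = 0.00964), Rgs5, a pericyte regulator of G proteins (log2 change 4.79, adjusted p = 0.00343) and Rbms3, an RNA-binding protein (log2 change 4.43, adjusted p = 0.00187). Heart and limb mesoderm contributed Hand2 (log2 change 4.39, adjusted p = 0.00491), and signalling genes Rspo3 (log2 change 4.44, adjusted p = 0.0104), Bmp5, a bone morphogenetic protein (log2 change 4.42, adjusted p = 0.0162) and Amer3, an APC-binding protein (log2 change 4.64, adjusted p = 0.00418). Inhbb fell most (signal 149 ± 43.2 to 4.77 ± 3.44, log2 change -5.21 ± 0.57, adjusted p = 0.000486). Myo1f (log2 change -4.49, adjusted p = 0.000826), Arc (log2 change -4.33, adjusted p = 0.00786) and Etv4 (log2 change -3.6, adjusted p = 0.00575) fell, and so did A2m (log2 change -3.37, adjusted p = 0.000686) and Ttc29 (log2 change -3.35, adjusted p = 0.0123). Further falls were in Tafa4, a secreted neural protein (log2 change -3.69, adjusted p = 0.0201) and Nkx6-3, a homeobox factor of stomach (log2 change -3.68, adjusted p = 0.00819). Dnajb13, a sperm axoneme protein (log2 change -3.51, adjusted p = 0.00926) and Nlrp4f, an oocyte protein (log2 change -3.28, adjusted p = 0.0128) completed them. Their log2 changes shrank, with 16 signal units added before the log, to between 1.51 and 3.40 for the rises and -2.96 and -1.34 for the falls. Lhx1 (1.89) then came behind Aplnr, Nrp1, Cdh11, Bmp5, Rspo3 and Rgs5. Not kept with 1 array left out (number of such arrays, highest adjusted p) were Cdh11 (1, 0.0515), Rspo3 (1, 0.0532), Bmp5 (3, 0.0778), Ttc29 (1, 0.0621), Dnajb13 (1, 0.0503) and Nlrp4f (1, 0.063), the highest p without LIF plus lithium replicate 3. For Tafa4 (3, 0.0861) it was reached without LIF-free plus lithium replicate 1.

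In the pluripotency list, 1 of 30 measured members rose, 24 fell and 5 did not pass. Pluripotency members that rose and fell adjusted over the list alone numbered 1 and 25 (median log2 change -1.2, camera adjusted p = 4.75e-16, 0.169 with an estimated correlation). The riser was Lin28a, a binder of let-7 precursors. Klf4 fell from 1615 ± 323 to 336 ± 65.4 (log2 change -2.27, adjusted p = 0.000486) and Pou5f1 from 2082 ± 328 to 748 ± 253 (log2 change -1.52 ± 0.29, adjusted p = 0.0059). Nanog fell from 1708 ± 309 to 815 ± 375 (log2 change -1.17 ± 0.30, adjusted p = 0.0246). Sox2 (log2 change -1.11, adjusted p = 0.0166), Zfp42 (log2 change -1.39, adjusted p = 7e-04) and Esrrb (log2 change -1.88, adjusted p = 0.0039) fell too. So did Tfcp2l1 (log2 change -1.57, adjusted p = 0.000486) and Tdgf1 (log2 change -1.93, adjusted p = 0.000486). Among LIF-STAT3 targets, 0 members rose, 8 fell and 13 did not pass among 21 measured, or 0 and 9 adjusted over the list alone. The LIF-STAT3 median log2 change was -0.67 (camera adjusted p = 2.23e-06, 0.175 with an estimated correlation). Lower members included Socs3 (log2 change -1.65, adjusted p = 0.00334), Gbx2 (log2 change -2.51, adjusted p = 0.00148) and Tbx3, a T-box factor that sustains Nanog (log2 change -1.2, adjusted p = 0.00285). Of Wnt targets, 19 were measured, of which 9 rose, 0 fell and 10 did not pass, or 14 and 0 adjusted over the list alone. Log2 changes of Wnt target genes had a median of 1.68 (camera adjusted p = 2.01e-05, 0.205 with an estimated correlation). Axin2 rose from 24 ± 10.5 to 75.9 ± 29.2 (log2 change 1.68 ± 0.38, adjusted p = 0.0125) and Dkk1 from 36.5 ± 9.12 to 206 ± 51.9 (log2 change 2.51, adjusted p = 0.00364). Tnfrsf19 (log2 change 2.83, adjusted p = 0.00466) and Cdx2, a caudal homeobox factor (log2 change 2.17, adjusted p = 0.0143) rose. With 1 array left out, calls ended (number of such arrays, highest adjusted p) for Nanog (4, 0.0981) and Sox2 (4, 0.0646), the highest p without LIF plus lithium replicate 3. For Axin2 (2, 0.066) and Cdx2 (3, 0.0712) it was reached without LIF-free plus lithium replicate 2.

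In the streak list, 6 of 14 measured members rose, 1 fell and 7 did not pass. Streak members that rose and fell adjusted over the list alone numbered 8 and 1 (median log2 change 1.43, camera adjusted p = 0.0088, 0.175 with an estimated correlation). Foxa2 (log2 change 1.66, adjusted p = 0.00383) and Snai1, a repressor of E-cadherin (log2 change 1.71, adjusted p = 0.00539) rose and Lefty2 (log2 change -1.33, adjusted p = 0.00303) fell. Among cardiac and lateral mesoderm genes, 18 were measured, of which 8 rose, 0 fell and 10 did not pass, or 9 and 1 adjusted over the list alone. Log2 changes of cardiac genes had a median of 0.84 (camera adjusted p = 0.00109, 0.227 with an estimated correlation). Kdr, the VEGF receptor of early mesoderm, rose from 3.83 ± 4.53 to 44.6 ± 7.04 (log2 change 4.13, adjusted p = 0.00483), with Tbx20 (log2 change 1.46, adjusted p = 0.00323) and Myh7, a slow myosin (log2 change 3.78, adjusted p = 0.00494). For primed-epiblast genes, 5 members rose, 1 fell and 11 did not pass among 17 measured, or 5 and 1 adjusted over the list alone. The primed-epiblast median log2 change was 0.76 (camera adjusted p = 0.0579). That list passed without LIF replicate 1 (adjusted p = 0.0332), LIF plus lithium replicate 1 (adjusted p = 0.0187), LIF plus lithium replicate 2 (adjusted p = 0.0383) or LIF-free plus lithium replicate 1 (adjusted p = 0.0134). Its risers included Fgf5 (log2 change 3.83, adjusted p = 0.0422), Fgf8, a growth factor of the streak (log2 change 3.93, adjusted p = 0.0158) and Sox4 (log2 change 1.77, adjusted p = 0.00512). Fgf5 missed the threshold after quantile normalisation (adjusted p = 0.0566). Of trophoblast genes, 11 of 15 measured members rose, 0 fell and 4 did not pass. Trophoblast members that rose and fell adjusted over the list alone numbered 14 and 0 (median log2 change 1.47, camera adjusted p = 1.26e-08, 0.169 with an estimated correlation). Krt18 (log2 change 1.60, adjusted p = 0.000675), Krt8 (log2 change 1.70, adjusted p = 0.00103) and Msx2, a homeobox target of BMP (log2 change 2.62, adjusted p = 0.00266) rose. In the epithelial-mesenchymal list, 21 were measured, of which 14 rose, 0 fell and 7 did not pass, or 15 and 0 adjusted over the list alone. Log2 changes of epithelial-mesenchymal genes had a median of 1.33 (camera adjusted p = 1.09e-07, 0.169 with an estimated correlation). Of fibroblast markers, 4 members rose, 0 fell and 9 did not pass among 13 measured, or 8 and 0 adjusted over the list alone. The fibroblast median log2 change was 1.57 (camera adjusted p = 0.000966, 0.227 with an estimated correlation). Risers were Col5a1 (log2 change 2.16, adjusted p = 0.00224), Col6a1 (log2 change 1.73, adjusted p = 0.00725), Col3a1 (log2 change 2.88, adjusted p = 0.00939) and Cxcl12 (log2 change 3.05, adjusted p = 0.00795). Gata6 did not pass (log2 change 0.18, adjusted p = 0.82). Calls that single arrays ended (their number, highest adjusted p) were Fgf5 (9, 0.171) and Fgf8 (3, 0.077), the highest p without LIF plus lithium replicate 3.

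Of germ cell genes with lithium present, 10 were measured, of which 0 rose, 6 fell and 4 did not pass, or 0 and 7 adjusted over the list alone. Log2 changes of germ cell genes had a median of -1.58 (camera adjusted p = 0.000145, 0.227 with an estimated correlation). The falls included Mael (log2 change -2.34, adjusted p = 0.00572), Ddx4 (log2 change -1.64, adjusted p = 0.00579) and Dazl (log2 change -2.47, adjusted p = 0.00852). Among imprinted genes, 12 of 19 measured members rose, 0 fell and 7 did not pass. Imprinted members that rose and fell adjusted over the list alone numbered 13 and 0 (median log2 change 1.23, camera adjusted p = 1.43e-06, 0.205 with an estimated correlation). Igf2, the fetal growth factor, rose (log2 change 2.29, adjusted p = 0.00302), with Cdkn1c (log2 change 2.46, adjusted p = 0.00103) and Dlk1, a Notch-like ligand (log2 change 3.14, adjusted p = 0.00138). Camera called 14 of the 22 lists, 9 up and 5 down, and 0 with an estimated correlation, the lowest such adjusted p being 0.169. Of 94 named genes that passed, 70 passed whichever single array was left out, 79 under all other alternatives and 65 throughout. Median centring ended 12 of the calls, Foxa2 among them. Leaving out LIF plus lithium replicates 1, 2 and 3 ended 2, 11 and 23 of the calls, and leaving out LIF-free plus lithium replicates 1, 2 and 3 ended 16, 16 and 2. With 16 signal units added before the log, other changes that moved over 1.5-fold were -1.82 for Gbx2, 1.42 for Cdx2, 1.06 for Foxa2, 0.90 for Snai1, 1.63 for Kdr, 1.44 for Myh7, 2.07 for Fgf5, 1.43 for Fgf8, 0.87 for Col6a1, 1.34 for Col3a1, 1.95 for Cxcl12, -1.44 for Dazl and 2.11 for Dlk1 (log2 change).

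The withdrawal comparisons without and with lithium share no arrays, but equal replicate numbers pair arrays across them, which the simulation leaves out. Their log2 changes correlated with r = 0.681 (covariance 0.339, against -0.000713 simulated for unchanged groups), and genes are not independent replicates. Of the called probe sets, 1093 were higher and 753 lower in both, where independent calls would give 109.8 and 52.1, and 0 were called in opposite directions. Of probe sets called without lithium, 99.2% changed the same way with it, with a slope of 0.943. Whether a gene's response to withdrawal differed with lithium is the interaction, which called 0 probe sets by limma (666 at an unadjusted p under 0.05).

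**Figure D3:**
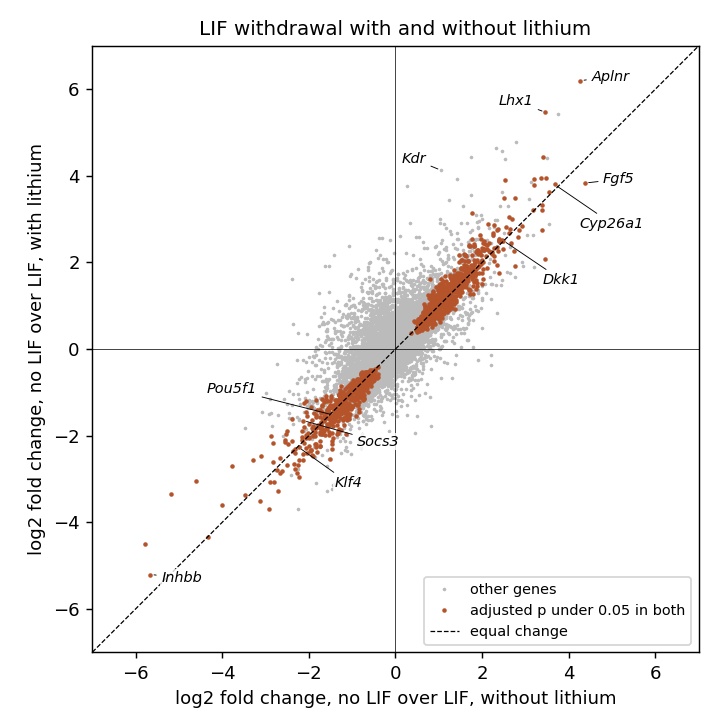
Log2 change on LIF withdrawal without lithium (horizontal) against that with lithium (vertical), one point per gene for 12737 genes. Orange points passed the threshold in both comparisons, the dashed line marks equal change, and no gene was called in opposite directions.

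Lithium added to LIF asks what it changes in cells already held in self-renewal. A response through beta-catenin would raise targets such as Axin2. No transcript passed: limma called 0 of 27022 probe sets, the lowest adjusted p was 0.999 (blocked 0.363), and 749 (2.77%, blocked 5.80%) had an unadjusted p under 0.05. The 3 genes with the smallest p, which missed the threshold (adjusted p = 0.999), were Camk1g, a calmodulin-dependent kinase (log2 change -2.03), Gpr20, an orphan receptor (log2 change -1.39), and Grem1, a BMP antagonist (log2 change -2.84). The LIF plus lithium signals of Camk1g and Grem1 lay under the filter signal. Values did not overlap in 828 genes (6.50%), where chance gives 10%. Without LIF plus lithium replicate 1, 2 probe sets passed, one of them for Tcl1b3 (log2 change 1.6, adjusted p = 0.0316). Log2 changes, with 95% intervals, were Pou5f1 -0.05 (-0.685 to 0.584), Nanog 0.08 (-0.577 to 0.73), Sox2 0.01 (-0.561 to 0.582), Zfp42 0.01 (-0.349 to 0.376), Klf4 0.09 (-0.408 to 0.597) and Esrrb 0.07 (-0.65 to 0.799). They were Axin2 0.03 (-0.785 to 0.84), Socs3 -0.34 (-0.955 to 0.273), Gata6 0.06 (-0.775 to 0.887) and Fgf5 0.21 (-2.22 to 2.65). Of all intervals, 59.5% lay within a 2-fold change either way, and 84.8% of those of the brighter probe sets.

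Wnt targets had 0 of 19 measured members past the threshold with lithium added to LIF, also adjusted over the list alone. Their median log2 change of -0.16 (camera adjusted p = 0.295) became 0.05 after quantile normalisation and 0.21 after median centring, where camera called the list down against all genes (adjusted p = 0.0233), as it did without LIF replicate 3 (adjusted p = 0.00302). Camera called 3 lists, all down, although none of their members passed over all genes. The streak list had a median log2 change of -0.51 (camera adjusted p = 0.0143, 0.467 with an estimated correlation). The cardiac list lay at -0.35 (camera adjusted p = 0.0143, 0.969 with an estimated correlation). The epithelial-mesenchymal list lay at -0.19 (camera adjusted p = 0.0176, 0.969 with an estimated correlation). Median centring turned the cardiac median to 0.02 and the epithelial-mesenchymal one to 0.18. Adjusted over the list alone, 0 members rose and 1 fell in the streak and in the epithelial-mesenchymal list, in each case Snai1 (log2 change -1.24). The calls rested on single arrays. Without LIF replicate 1 the adjusted p was 0.545, 0.564 and 0.564 in that order. Without LIF plus lithium replicate 2 it was 0.122 and 0.175 for the first 2, and without replicate 3 it was 0.717 for the last. A pseudocount of 16 also ended all 3 calls (adjusted p = 0.155, 0.155 and 0.125), as did array weights (0.169, 0.12 and 0.446), no filter, the filter at the 60th percentile and the mean over a gene's probe sets. Fry called 0 lists.

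Lithium without LIF asks whether it holds back, or redirects, the changes that follow LIF withdrawal. No transcript of the naive network, of Wnt targets or of a lineage passed the threshold. limma called 0 of 27022 probe sets, the lowest adjusted p was 1, and 347 (1.28%) had an unadjusted p under 0.05. Smallest in p, and missing the threshold (adjusted p = 1), were Gpr3, a receptor that raises cyclic AMP (log2 change 2.55), Bnip5 (log2 change 2.28) and the keratin-associated Krtap12-1 (log2 change 2.0). Values did not overlap in 785 genes (6.16%). The 10% that chance gives for unpaired arrays is again not the level for paired ones. Log2 changes with 95% intervals were Pou5f1 -0.13 (-0.768 to 0.501), Nanog -0.26 (-0.914 to 0.393), Sox2 -0.05 (-0.622 to 0.52), Zfp42 -0.27 (-0.628 to 0.0969), Klf4 0.07 (-0.435 to 0.571) and Esrrb 0.11 (-0.617 to 0.832). They were Axin2 0.26 (-0.556 to 1.07), Socs3 0.14 (-0.47 to 0.758), Gata6 -0.49 (-1.32 to 0.344) and Fgf5 -0.33 (-2.76 to 2.1). Within a 2-fold change either way lay 62.2% of all intervals and 87.8% of those of the brighter probe sets. None of the 22 lists was called (lowest camera adjusted p = 0.256), but single arrays gave calls, 4 of them, all down, without LIF-free plus lithium replicate 2. Wnt targets had 0 of 19 measured members past the threshold, also adjusted over the list alone. Their median log2 change was 0.01, their mean -0.03, and the test pointed down (camera adjusted p = 0.793). The pluripotency list had a median log2 change of -0.05 (camera adjusted p = 0.705). Single arrays turned it either way: it was called up at 0.16 without LIF-free plus lithium replicate 1 (adjusted p = 0.00246), and down at -0.23 without LIF-free plus lithium replicate 3 (adjusted p = 0.000314).

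The interaction asks whether the response to LIF withdrawal was larger or smaller with lithium. limma called 0 probe sets (lowest adjusted p = 0.999), and 666 (2.46%) had an unadjusted p under 0.05. The median 95% half-width was 0.89 log2 units, and 40.9% of intervals lay within a 2-fold difference. Smallest in p were Gpr3 (log2 difference 4.02), Camk1g (log2 difference 2.51) and Pou5f2, a germ cell POU factor (log2 difference 3.55), the first 2 with a condition under the filter signal. The log2 difference of Pou5f1 was -0.08 and that of Axin2 0.23 (95% interval -0.92 to 1.38). No list was called (lowest camera adjusted p = 0.118), but this was not stable: 27 of 483 alternative values gained a call.

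The average effect asks what lithium did across both LIF states, with the narrowest intervals of the comparisons. limma called 0 probe sets (lowest adjusted p = 1), and 340 (1.26%) had an unadjusted p under 0.05. Grem1 (log2 change -1.72), Tmem88b (log2 change -1.21) and Acsbg3 (log2 change -1.31) had the smallest p. Log2 changes with 95% intervals were Axin2 0.14 (-0.432 to 0.717), Pou5f1 -0.09 (-0.541 to 0.357) and Nanog -0.09 (-0.554 to 0.37). They were Sox2 -0.02 (-0.424 to 0.383), Klf4 0.08 (-0.275 to 0.437) and Zfp42 -0.13 (-0.382 to 0.13). Of all intervals, 77.4% lay within a 2-fold change, and 96.2% among the brighter probe sets. Camera called the streak list down (median log2 change -0.29, adjusted p = 0.000887, 0.152 with an estimated correlation), a call that ended without LIF replicate 1 (adjusted p = 0.0641), with array weights (0.0594) or with the filter at the 60th percentile (0.168). It called the primed-epiblast list down (median log2 change -0.14, adjusted p = 0.0322, 0.981 with an estimated correlation). That call ended without LIF replicate 1 (adjusted p = 0.669), LIF replicate 2 (0.0529), LIF plus lithium replicate 3 (0.663), LIF-free replicate 2 (0.134) or LIF-free plus lithium replicate 1 (0.213), and with array weights (0.213), the filter at the 60th percentile (0.211), no filter, quantile normalisation or the mean over a gene's probe sets. Lithium with LIF and lithium without LIF share no arrays, and their log2 changes correlated with r = -0.122 (covariance -0.0173, against -0.00113 simulated for unchanged groups).

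The last comparison asked whether lithium can stand in for LIF, by setting LIF-free cells with lithium against cells with LIF alone. Naive transcripts fell, and Fgf5, simple keratins and several imprinted and Wnt target genes rose. limma called 2503 probe sets, 1480 higher and 1023 lower in LIF-free cells with lithium, and 1430 changed at least 2-fold. By gene, 947 were higher and 619 lower, and in 3887 genes (30.5%) the values did not overlap, where chance gives 10%. After median centring 69.4% of 1061 calls were higher, against 59.1% as deposited. The count was 3759, 1050 and 1468 without LIF replicates 1, 2 and 3, and 1087 and 1085 without LIF-free plus lithium replicates 1 and 2. This comparison shares its LIF arrays with withdrawal without lithium, and the log2 changes correlated with r = 0.861, against 0.501 simulated for unchanged groups. It shares its LIF-free plus lithium arrays with withdrawal with lithium (r = 0.844, against 0.499 simulated). Here too the Gapdh ratio was lower without overlap (0.816 with LIF, 0.783 without), and the 18S signal was 659 and 1077, with overlap.

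Fgf5 had the largest log2 rise, from low LIF signals (signal 12.7 ± 17.2 to 104 ± 48, mean ± SD, n = 3, log2 change 4.05, adjusted p = 0.0407). Other large rises were Rtp4 (log2 change 3.61, adjusted p = 0.0255), Vdr (log2 change 3.6, adjusted p = 0.00215), Usp18 (log2 change 3.56, adjusted p = 0.0138) and Foxa1 (log2 change 3.54, adjusted p = 0.0268). They included Bmp5 (log2 change 3.58, adjusted p = 0.049), Evx1 (log2 change 3.43, adjusted p = 0.0371) and Cyp26a1 (log2 change 3.38, adjusted p = 0.00403). Lhx1 (log2 change 3.33, adjusted p = 0.0322) and Nhsl2, an actin regulator (log2 change 3.34, adjusted p = 0.0151) completed them. Inhbb fell most (signal 155 ± 73.6 to 4.77 ± 3.44, log2 change -5.19, adjusted p = 0.000975). Myo1f (log2 change -4.45, adjusted p = 0.00127), Nkx6-3 (log2 change -3.84, adjusted p = 0.00862) and Arc (log2 change -3.56, adjusted p = 0.0246) fell. Etv4 (log2 change -3.46, adjusted p = 0.00913) and Dnajb13 (log2 change -3.43, adjusted p = 0.0133) fell too. So did Sema4a, a semaphorin (log2 change -3.35, adjusted p = 0.00505) and Rfx2, a cilia factor (log2 change -3.32, adjusted p = 0.0221). S100a7l2, a calcium-binding protein (log2 change -3.24, adjusted p = 0.0152) and Cxcl14, a chemokine (log2 change -3.17, adjusted p = 0.0247) completed the falls. Their log2 changes shrank, with 16 signal units added before the log, to between 1.22 and 2.57 for the rises and -2.96 and -0.89 for the falls. Fgf5 (2.14) then came behind Usp18 and Cyp26a1 (2.41). Not kept with 1 array left out (number of such arrays, highest adjusted p) were Fgf5 (9, 0.151), Arc (4, 0.108), S100a7l2 (2, 0.0574) and Cxcl14 (4, 0.101), the highest p without LIF replicate 3. For Rtp4 (5, 0.0958), Usp18 (3, 0.0614), Lhx1 (4, 0.131) and Rfx2 (4, 0.0898) it was reached without LIF-free plus lithium replicate 2. For Foxa1 (4, 0.0988), Evx1 (5, 0.142) and Dnajb13 (2, 0.0595) it was reached without LIF replicate 2. For Bmp5 (11, 0.18) and Nhsl2 (3, 0.0731) it was reached without LIF-free plus lithium replicate 1.

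In the pluripotency list, 0 members rose, 24 fell and 6 did not pass among 30 measured, or 1 and 25 adjusted over the list alone. The pluripotency median log2 change was -1.26 (camera adjusted p = 3.51e-16, 0.195 with an estimated correlation). Klf4 fell from 1531 ± 395 to 336 ± 65.4 (log2 change -2.17, adjusted p = 0.000975) and Pou5f1 from 2281 ± 989 to 748 ± 253 (log2 change -1.57, adjusted p = 0.00663). Nanog (log2 change -1.09, adjusted p = 0.0401), Sox2 (log2 change -1.10, adjusted p = 0.0215) and Zfp42 (log2 change -1.38, adjusted p = 0.00113) fell. Esrrb (log2 change -1.80, adjusted p = 0.00652), Tfcp2l1 (log2 change -1.56, adjusted p = 0.000975) and Tdgf1 (log2 change -1.96, adjusted p = 0.000975) fell too. Socs3 (log2 change -1.99, adjusted p = 0.0021) was lower. Of Wnt targets, 19 were measured, of which 5 rose, 0 fell and 14 did not pass, or 11 and 0 adjusted over the list alone. Log2 changes of Wnt target genes had a median of 1.05 (camera adjusted p = 9.01e-05, 0.292 with an estimated correlation). Axin2 (log2 change 1.71, adjusted p = 0.0147), Dkk1 (log2 change 2.44, adjusted p = 0.00566) and Cdx2 (log2 change 1.85, adjusted p = 0.0362) rose. In the trophoblast list, 10 members rose, 0 fell and 5 did not pass among 15 measured, or 14 and 0 adjusted over the list alone. The trophoblast median log2 change was 1.32 (camera adjusted p = 2.91e-09, 0.195 with an estimated correlation). Krt18 (log2 change 1.45, adjusted p = 0.00141) and Gata3 (log2 change 2.50, adjusted p = 0.00229) were higher. Of imprinted genes, 9 of 19 measured members rose, 0 fell and 10 did not pass. Imprinted members that rose and fell adjusted over the list alone numbered 14 and 0 (median log2 change 1.05, camera adjusted p = 1.24e-06, 0.292 with an estimated correlation). Cdkn1c (log2 change 2.18, adjusted p = 0.00264) and Igf2 (log2 change 1.93, adjusted p = 0.00919) rose. Gata6 did not pass (log2 change 0.23, adjusted p = 0.791). Camera called 13 of the 22 lists, 8 up and 5 down, and 0 with an estimated correlation, the lowest such adjusted p being 0.195. Of 84 named genes that passed, 40 passed whichever single array was left out, 47 under all other alternatives and 35 throughout. Median centring ended 18 of the calls, Nanog and Sox2 among them. Leaving out LIF replicates 1, 2 and 3 ended 1, 40 and 29 of the calls, and leaving out LIF-free plus lithium replicates 1, 2 and 3 ended 29, 35 and 11. With 1 array left out, calls ended (number of such arrays, highest adjusted p) for Nanog (6, 0.135), the highest p without LIF-free plus lithium replicate 1. For Sox2 (4, 0.0806) it was reached without LIF replicate 3. For Axin2 (3, 0.074) it was reached without LIF-free plus lithium replicate 2. For Cdx2 (5, 0.144) it was reached without LIF replicate 2. With 16 signal units added before the log, other changes that moved over 1.5-fold were 1.24 for Cdx2 and 1.58 for Gata3 (log2 change).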

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

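All alternatives here were planned. The counts of 0 called probe sets for lithium with LIF, lithium without LIF, the interaction and the average lithium effect (limma) stayed 0 under every alternative that kept all arrays. Counts for withdrawal without lithium, withdrawal with lithium and lithium without LIF against LIF alone stayed within 1.5 times of 2515, 3368 and 2503 under quantile normalisation, a pseudocount of 16 and either filter. Median centring gave 1560, 1490 and 1061. Array weights gave 7870, 6887 and 7454. Without the intensity trend the first was 1674, and with only the compared arrays the first and last were 1168 and 1024. For these moves the cause was not tested. With the replicate number as a block, which takes out differences between numbers, they were 5260, 5938 and 5073, all calls made without the block were kept, and lithium with LIF, lithium without LIF, the interaction and the average effect stayed at 0 (1567, 824, 1604 and 733 probe sets at an unadjusted p under 0.05). Withdrawal with lithium and lithium without LIF against LIF alone are not paired by the check (correlations 0.451, 0.0972 and 0.379, and 0.385, 0.0316 and 0.181). As a hint from the data, 5 and 4 of their 6 arrays were closest to the array of their own number. The block brought the primed-epiblast list past the threshold in withdrawal with lithium (adjusted p = 0.0435), and besides 6 named-gene calls gained and the counts it changed no other call.

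Leaving out 1 array gave 1039 to 3950 calls in withdrawal without lithium, with moves over 1.5 times without LIF replicates 1 (3950), 2 (1075) and 3 (1506) and LIF-free replicates 1 (1324), 2 (1039) and 3 (1569). Withdrawal with lithium ran from 1360 to 4311, with such moves without LIF plus lithium replicates 2 (1806) and 3 (1360) and LIF-free plus lithium replicates 1 (1499) and 2 (1522). Lithium without LIF against LIF alone ran from 1050 to 3759, with such moves without LIF replicates 1 (3759), 2 (1050) and 3 (1468) and LIF-free plus lithium replicates 1 (1087) and 2 (1085). Lithium with LIF ran from 0 to 2 (2 without LIF plus lithium replicate 1, with 462 to 1702 at an unadjusted p under 0.05). Lithium without LIF, the interaction and the average effect stayed at 0. For the counts that grew the cause was not tested. Among lists, the pluripotency median for lithium without LIF ran from -0.23 (called down without LIF-free plus lithium replicate 3) to 0.16 (called up without LIF-free plus lithium replicate 1). The germ cell median there ran from -0.29 to 0.38 (called up without LIF-free plus lithium replicate 1), and the pluripotency median of the average effect from -0.11 (called down without LIF-free plus lithium replicate 3) to 0.085. Of 1934, 2054 and 1931 alternative values of named genes in the 3 comparisons with calls, 1724, 1943 and 1683 kept direction and side of the threshold, 197, 105 and 241 lost the call, 13, 6 and 7 gained it and 0 reversed. Camera's list calls were lost most often with an estimated correlation (47 of 154 values), which leaves none called. The filter at the 60th percentile ended 13 of 147: streak, primed epiblast, fibroblast and Hox in withdrawal without lithium, streak and cell cycle in withdrawal with lithium, all 3 calls of lithium with LIF, both calls of the average effect, and fibroblast and Hox in the last comparison. Array weights ended 5, all 3 calls of lithium with LIF and both of the average effect. List calls were also gained. Lithium with LIF gained 23 of 483 values: 5 with median centring and 6, 5 and 7 without LIF replicates 2 and 3 and LIF plus lithium replicate 1. The interaction gained 27: 7 with median centring, 6 and 4 without LIF replicates 2 and 3, 4 without LIF-free plus lithium replicate 3 and 6 elsewhere. The average effect gained 23, among them 6 without LIF-free replicate 3 and 6 without LIF-free plus lithium replicate 1, and lithium without LIF gained 6, all down, besides the 2 called up above. Signal near background set the other limit: at 4-fold, simulated recovery in withdrawal without lithium was 67.5% over all probe sets and 90.1% over the brighter ones.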

Other observations

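Tests of the beta-catenin targets, of exchanges between same-numbered arrays, of RNA degradation, of cultures of one number, and of blood cells and fibroblasts were chosen after the results were seen, as were the interferon and class I lists and the order of replicates. The splits of arrays, the exchange of labels in a single LIF state and the scaling test were planned.

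Several interferon-stimulated genes and genes of class I antigen presentation were higher without LIF. Of 30 measured interferon-stimulated genes 11 rose and 1 fell without lithium (median log2 change 0.92, camera adjusted p = 3.52e-06, adjusted p = 0.0707 with an estimated correlation), and of 15 class I genes 8 rose and 0 fell (median 0.89, camera adjusted p = 2.91e-06, adjusted p = 0.0707 with an estimated correlation), B2m among them (signal 595 ± 132 to 1520 ± 290, log2 change 1.36). Admixed feeder fibroblasts stay open. The highest mean signal of Col1a1, Col1a2 and Col3a1 without LIF was 30.9, but signals of different probe sets do not measure relative abundance. The fibroblast list was called up (median log2 change 1.13, camera adjusted p = 0.00767, 0.345 with an estimated correlation), and with lithium Col3a1 rose (log2 change 2.88). Admixed blood cells stay open too, since 1 member of the blood and endothelium list, Kdr, rose in withdrawal with lithium, and Kdr is also a gene of early mesoderm. No biological explanation was tested, and a gain of class I expression on differentiation is only a hypothesis.

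No probe set was called for lithium in either LIF state (749 with LIF and 347 without at an unadjusted p under 0.05, limma). A large lithium effect hidden by exchanged labels of same-numbered arrays is argued against. All 32 splits parting every such pair in both LIF states, the real one included, called 0 for the interaction and average effect. Single states gave 0 too. A smaller effect may go uncalled and stays open. Exchanges across numbers stay open: no other split of a single LIF state called more than 9 probe sets. Exchanges in both states called up to 2654 and 703 while parting only 1 pair per state. A rise of beta-catenin targets of 2-fold or more, hidden by the spread, is argued against for 15 of 19 measured targets. Their unblocked 95% intervals for the average effect end below a 2-fold rise, with Axin2 highest at 0.14. For single states this held for 12 targets with LIF and 9 without. Whether the stated lithium dose acted on the cells at all was not tested and stays open.

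Replicate 1 lay further along the LIF withdrawal axis than replicate 3 in all 4 conditions, where the axis is the mean of the probe sets that rose minus that of those that fell in the withdrawal comparison of the other lithium state. The mean difference was 0.518 log2 units, 24.1% of the mean effect of withdrawal (exact permutation p = 0.00463 for any difference between the numbers, over 1296 reorderings within conditions, the smallest they can give). Differences in scaling are argued against, since the mean was 0.564 after quantile normalisation. RNA degradation stays open: replicate 1 had the higher actin 3 prime to 5 prime ratio in 4 of 4 conditions but the lower Gapdh ratio in 4 of 4. Cultures of one number that had moved further from the pluripotent state stay open: the pluripotency list was lower in replicate 1 in all 4 conditions (mean of medians -0.399), but 22 and 24 of its 30 members fell in the withdrawal comparisons and so belong to the axis, and the test restates it.

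The 6 arrays of a comparison make 10 splits, the real one included, too few for a share under 0.05. The real split called 2515, 3368 and 2503 probe sets in withdrawal without lithium, withdrawal with lithium and lithium without LIF against LIF alone, the highest other called 0 in each, and 1 of 10 splits, the real one, reached the real count. For lithium with LIF the real count was 0 and the highest other 9, and for lithium without LIF 0 and 0. Every split reaches a count of 0 (10 of 10 here, and 100 of 100 drawn splits of the lithium labels for the interaction and the average lithium effect), so these tallies say nothing about chance. Among splits that part as many pairs as the real one the highest others were 0 for the paired comparisons, and the split with 9 parts 1 pair. The highest other for the interaction called 2654, with LIF replicates 1 and 2, LIF plus lithium replicate 1, LIF-free replicates 2 and 3 and LIF-free plus lithium replicate 3 on one side. For the average effect it called 703, with all replicate 1 arrays, LIF replicate 3 and LIF-free plus lithium replicate 2 on one side. Both splits kept the replicate 1 arrays of each LIF state together, so replicate number may underlie such counts.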
